A study of Mus musculus with 2 samples.

How the data were processed

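Splenic T cells of 2 arthritic ZAC mice that also carried a Foxp3-GFP reporter were profiled as 2 single-cell libraries, 1 of regulatory T cells (Treg) and 1 of conventional T cells (Tconv). ZAC is the name of the mouse model in the labels, and its strain background is not given in the sources used here. Per the labels, the Tconv cells were sorted as CD3-positive and GFP-negative, and gene expression and receptor libraries were made with the 10x Genomics system. The protocol text of the Treg library repeats the Tconv sort, so the Treg gate is not given separately and the group was taken from the cell type label. The Tconv sort does not select CD4 and so does not exclude CD8 T cells, gamma-delta T cells or NKT cells.

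The deposited matrices hold a raw UMI count per gene and barcode, as whole numbers, for 32285 genes and 2 hashtag antibody features named ZAC1 and ZAC2. Cell Ranger 5.0, Seurat 4.0 and the genome build GRCm38 are named by the submitters; which steps each tool took, and the annotation release, are not given in the sources used here. In a GENCODE annotation of GRCm38, 32235 of the gene IDs were found, 31502 of them with the same symbol, and 78 features share a symbol with another feature. The Treg library held 4375 barcodes with 16204488 gene UMIs and the Tconv library 3265 barcodes with 12960437. Hashtag UMIs were 54.6% of all UMIs in Treg and 57.6% in Tconv and were left out of every gene total. The receptor tables were not analysed here, and only V segments counted in the expression libraries were used.

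Cells were kept with at least 300 genes, at most 10% mitochondrial UMIs and no doublet call by Scrublet. In Treg 171 barcodes were under the gene minimum, 90 were over the mitochondrial limit, 0 were called doublets and 4119 were kept, with a median of 2730 UMIs and 1293 genes per cell. In Tconv these counts were 158, 69 and 19, and 3028 cells were kept, with medians of 3136 UMIs and 1363 genes. Scrublet barely worked here, since 153 Treg and 152 Tconv barcodes carried both hashtags. A barcode was assigned to a hashtag when it held at least 500 hashtag UMIs, of which at least 90% were of that hashtag. Of the Treg barcodes 2230 were assigned to ZAC1, 1741 to ZAC2 and 251 to none. Of the Tconv barcodes 1452 were assigned to ZAC1, 1449 to ZAC2 and 212 to none. The hashtags were taken as the 2 mice, which the labels do not state outright.

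The comparisons were of all kept cells and of Cd4-gated cells, which had at least 1 Cd4 UMI and no Cd8a or Cd8b1 UMI (1175 Treg and 1050 Tconv cells). UMIs were summed per library and scaled by the library's gene total to CPM. With 1 library per group the planned comparison had no test: genes with at least 50 UMIs over both libraries were called at a 2-fold ratio, with exact 95% Poisson intervals and a floor of 3 counts for a gene at 0 in a library. Intervals and the floor cover counting error only. The designs of these comparisons, 18 function lists, 18 marker lists, the rule for named genes and most alternatives were fixed before the data were examined.

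After the files had been seen, the UMIs of the cells with a single hashtag were summed into 4 hashtag-by-library sets and tested with the edgeR quasi-likelihood test (TMM factors, filterByExpr with a minimum count of 10, Benjamini-Hochberg adjusted p under 0.05, two-sided). Genes are said to have risen or fallen in Treg relative to Tconv only where they passed this test. Each group then had n = 2 hashtag sets of 1 sort and 1 lane, so lane and cell type cannot be told apart and the p-values measure the spread between hashtag sets only. To check whether a hashtag marks the same mouse in both libraries, the deviation of each gene from its library mean was compared between libraries. The correlation across genes was 0.0472 in all cells and 0.0699 in Cd4-gated cells. Counting error in genes with few UMIs can hide a shared mouse, so these low values do not show that the hashtags mark different mice. The hashtag was used as a block only as an alternative, so the main test ignores such a pairing. The common biological coefficient of variation was 0.175 and 0.0879.

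Named genes were the 10 with the highest and the 10 with the lowest ratio in all cells, and 12 of each in Cd4-gated cells, among genes with at least 50 CPM in the higher library and at least 100 UMIs over both. Receptor and immunoglobulin segments, unnamed gene models and the gate genes were left out. Up to 4 members per list with the largest absolute log2 ratio, the 5 V genes per chain with the largest difference in share, and Foxp3, Il2ra, Cd4, Cd8a and Cd8b1 were named in addition. Some planned results, among them a split of the gated cells, are not reported here. Genes outside this rule were chosen after their values had been seen, as were the cluster genes, the cytokine combinations and the extra gene groups. For each list the median log2 ratio was set against 10000 random lists matched on mean expression in 20 bins, and members at least 1.5-fold higher or lower were counted. Shares of cells with a UMI were computed after thinning each cell to 1500 UMIs, with shallower cells left out, and have exact Clopper-Pearson intervals. For a share of 0, the limit given is 3 cells over the number of cells, which is tighter than the upper end of that interval. Cells with at least 4 B cell markers and no Cd3 UMI served to measure free RNA. Leaving out cells with a Cd3 UMI can also leave out cells with free T cell RNA, so shares in these B-marker cells may be too low.

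Each Cd4-gated cell was assigned to the Trbv and the Trav gene with the most UMIs, with ties left out. Each library was clustered by itself (counts scaled to 10000 per cell, 2000 variable genes without receptor segments, 30 components, 15 neighbours, Leiden resolution 1.0). A cluster was named when at least 2 markers of a type were among its 10 leading genes and at least 3 were detected; after the first clusters had been seen, a T cell name was refused where at least 2 leading genes marked another type. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.

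On simulated data with known changes, edgeR recovered 78% of 50 genes changed 2-fold and 100% of those changed 4-fold in the Cd4-gated design, with 4 false calls among 9028 genes tested. In the all-cells design it recovered 36% and 100%, with 5 false calls among 11236. The 2-fold rule found 100% of genes set 4-fold apart, and called 11 of 8902 genes in the Cd4-gated and 7 of 11196 in the all-cells simulation although their levels had been left equal. A list of 15 genes shifted by 0.5 log2 units reached percentile 100, and 4% of 200 unshifted lists fell outside the random range. The simulated counts for the 2-fold rule and the lists held counting error only, and those for edgeR 1 common spread for all genes. No difference between lanes was simulated, so these rates of false calls cannot be taken as those of the real libraries.

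The alternatives tried were edgeR TMM and median-of-ratios scaling, library totals without ribosomal protein, mitochondrial and receptor genes, equal weight per cell, looser and stricter cell filters, cells with at least 2 B cell or myeloid markers left out, gene minimums of 10 and 200 UMIs, thinned cells, other Cd4 gates, other thinning depths, other V gene assignments and other cluster resolutions. A T cell gate (at least 2 Cd3 UMIs, under 2 B cell or myeloid markers, haemoglobin under 1% of UMIs), the removal of cells with both hashtags or none, a haemoglobin filter and every alternative to the edgeR test were added after the data had been seen.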

Results

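To compare regulatory with conventional T cells of arthritic spleens, 4119 Treg and 3028 Tconv cells were examined, first within the 1175 Treg and 1050 Tconv cells that had a Cd4 UMI and no Cd8a or Cd8b1 UMI. The median Cd4-gated cell held 3373 UMIs in Treg and 3344 in Tconv, and the gated sums held 5072059 and 4000924 UMIs. There was 1 library per group. Values with a spread are the mean ± SD over the n = 2 hashtag sets of each library, and the edgeR test compared these sets.

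Foxp3, the transcription factor behind the reporter used for sorting, reached 581 CPM in Cd4-gated Treg cells and 1.25 in Tconv cells (ENSMUSG00000039521, chromosome X from 7573644 to 7595245, GRCm38). The log2 ratio was 8.86 (95% counting interval 7.64 to 10.48), the hashtag sets gave 597 ± 29.6 and 1.35 ± 0.464, and the edgeR log2 fold change was 8.70 ± 0.192 (SE; adjusted p 7.08e-10). Because the reporter follows Foxp3, this ratio reflects the sort. Il2ra, the high-affinity IL-2 receptor chain (ENSMUSG00000026770, chromosome 2 from 11642807 to 11693193), was 14.8-fold higher at 236 against 16 CPM (243 ± 22.9 and 16.2 ± 3.90 over hashtag sets; adjusted p 5.80e-08). The inhibitory receptor gene Ctla4 (ENSMUSG00000026011, chromosome 1 from 60887000 to 60915832) rose 16.8-fold, to 324 from 19.2 CPM (log2 4.07, 3.74 to 4.42; adjusted p 1.25e-07).

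The genes with the highest ratios after Foxp3 included receptors and products of effector Treg cells. Klrg1, a receptor of terminally differentiated lymphocytes (ENSMUSG00000030114, chromosome 6 from 122270596 to 122282882), rose 112-fold (364 against 3.25 CPM; 369 ± 6.65 and 3.10 ± 3.59 over hashtag sets; adjusted p 5.01e-08). The cytotoxic protease gene Gzmb (ENSMUSG00000015437, chromosome 14 from 56258838 to 56262260) rose 24.8-fold, from 17.2 to 428 CPM (log2 4.63, 4.29 to 5.0; adjusted p 1.11e-06). The enkephalin precursor gene Penk rose 72-fold and the membrane antigen gene Ly6a 27.5-fold, the latter with an edgeR SE of 0.479. The log2 ratios of the rest of the 12 highest were Neb (5.09), Rln3 (4.49), Tnfrsf9 (4.45), Csrp2 (4.30) and Dusp4 (3.86), and all 12 rose.

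In the opposite direction, the genes with the lowest ratios included those of type 17 helper cells, an IL-17-producing class tied to joint inflammation. Il22 (ENSMUSG00000074695, chromosome 10 from 118204942 to 118210047) was 58.8-fold lower in Treg, at 1.97 against 116 CPM (log2 -5.88, -6.95 to -4.99; adjusted p 6.57e-07). Il17a (ENSMUSG00000025929, chromosome 1 from 20730905 to 20734496) was 27.8-fold lower, at 6.31 against 175 CPM (6.04 ± 3.70 and 185 ± 2.16 over hashtag sets; adjusted p 1.02e-07). The chemokine receptor gene Cxcr6 (ENSMUSG00000048521, chromosome 9 from 123806475 to 123811760) fell 23.7-fold, to 13 from 309 CPM. The helper ligand gene Cd40lg was 10.9-fold lower (15.8 against 172 CPM) and Tnfsf8 13.4-fold lower. Further genes among the 12 lowest, all of which fell, were Pdlim4 (-5.07), Il17re (-4.91), Stmn2 (-4.05), Il17f (-3.94) and Tmem176b (-3.42), as log2 ratios. S100a9, a neutrophil gene that was also among the 12 lowest (log2 -4.90), was an exception, since 243 of its 259 Tconv UMIs came from 2 barcodes that carried both hashtags. It was not tested in edgeR, and its log2 ratio was -0.49 and -0.98 within the hashtag sets.

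Tcf7, the transcription factor gene of naive and memory-like T cells (ENSMUSG00000000782, chromosome 11 from 52252371 to 52283014), was 10.9-fold lower in Treg, at 30.4 against 330.2 CPM (30.5 ± 2.12 and 339 ± 11.5 over hashtag sets; adjusted p 1.55e-08). The IL-2 gene Il2 was at 0.591 CPM in Treg and 29.5 in Tconv (3 and 118 UMIs; log2 -5.64, -7.94 to -4.06).

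**Figure D1:**
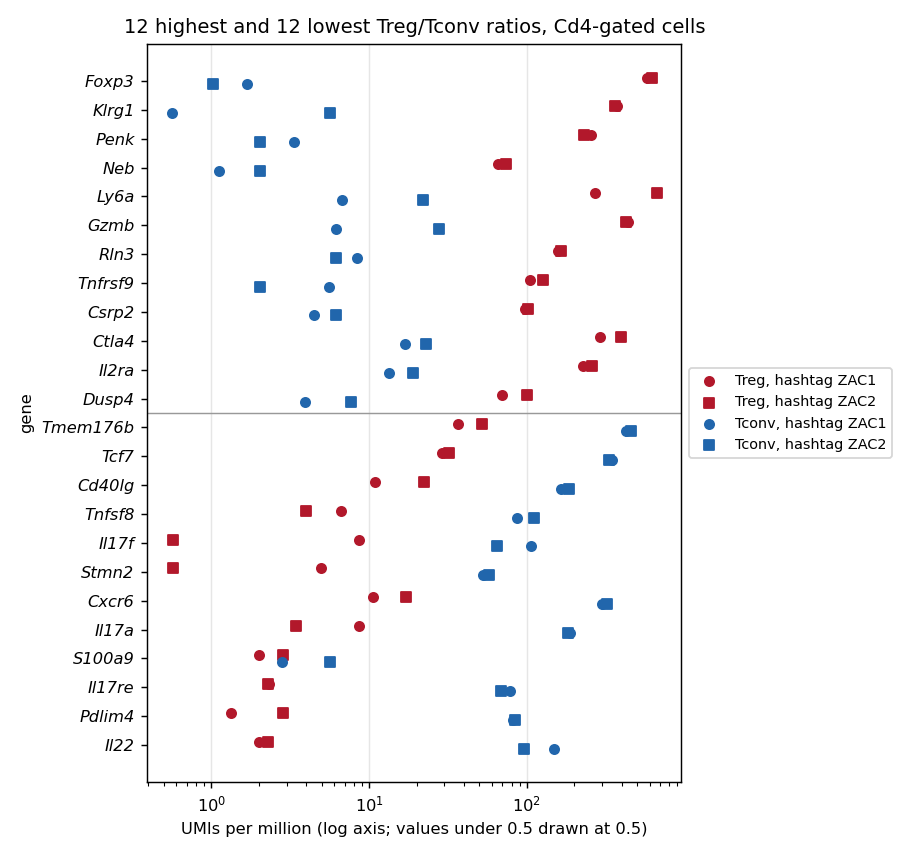
CPM (log axis) of named genes in Cd4-gated cells, with 1 point per hashtag set of each library and values under 0.5 drawn at 0.5. Foxp3 averaged 597 ± 29.6 and 1.35 ± 0.464 (SD, n = 2) in the Treg and Tconv sets.

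Of 8941 genes with enough UMIs, 584 were at least 2-fold higher in Cd4-gated Treg cells and 440 at least 2-fold lower. Of these, 508 and 375 passed edgeR in the same direction, and 384 and 295 were at least 2-fold apart within both hashtag sets. In edgeR 1138 genes rose and 1006 fell of 9105 tested. The share of higher genes among the 2-fold genes depended on the scaling, at 57.0% with library totals and 46.8% when ribosomal protein, mitochondrial and receptor genes were left out of the totals (497 higher and 564 lower). It was 63.6% without cells with at least 2 B cell or myeloid markers (547 higher and 313 lower).

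Of the gene lists, the core Treg list had a median log2 ratio of 3.20 in Cd4-gated cells, at percentile 100 of matched random lists (middle 95% -0.15 to 0.31). Within it, 15 of 16 tested members rose and 1 fell (15 up and 1 down adjusted over the list alone). Gpr83 (3.98), Ikzf2 (3.70) and Itgae (3.0) rose, and the ectonucleotidase gene Nt5e fell (-1.39). The Treg effector list had a median of 2.52 (percentile 100), and 10 of 12 tested members rose and 2 did not pass (11 up and 0 down adjusted over the list alone). Besides Klrg1 and Gzmb, the growth factor gene Areg (3.43; 99.8 against 9.25 CPM) and the IL-35 subunit gene Ebi3 (2.79) rose. The cell cycle list had a median of 1.35 (percentile 100), and 17 of 17 tested members rose (17 up and 0 down adjusted over the list alone). The proliferation marker gene Mki67 (ENSMUSG00000031004, chromosome 7 from 135689784 to 135716361) was 2.89-fold higher, at 359.6 against 124 CPM (355 ± 32.1 and 125 ± 32.3 over hashtag sets), beside Stmn1 (1.61), Pclaf (1.52) and Top2a (1.51). The gate let in a larger share of cycling than of other Treg cells. A Cd4 UMI was found in 54.5% and 54.9% of the Treg cycling clusters described below. It was found in 26.2%, 37.7% and 37.8% of the clusters of 814, 1073 and 603 cells. In Tconv the share was 60.8% in the cycling and 52.1% in the Th17-like cluster. Cycling cells thus weighed more in the gated Treg sum. The list median was 0.48 in all cells.

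The naive and quiescent list had a median of -0.64 (percentile 0), and 3 of 14 tested members rose, 8 fell and 3 did not pass (4 up and 8 down adjusted over the list alone). Its members were split, with Id3 (1.02) and S1pr1 (0.45) up, and Tcf7, Igfbp4 (-3.19), Actn1 (-1.11), Il7r (-1.09) and Ccr7 (-0.92) down. The activated and memory list was at 0.29, inside its random range (-0.15 to 0.30), and 9 of 18 tested members rose, 4 fell and 5 did not pass (9 up and 5 down adjusted over the list alone). S100a10 (1.42) and Icos (1.32) rose while Id2 (-2.25) and Lgals3 (-1.89) fell. The Th17 list had the lowest median of the 18 lists (-3.40, percentile 0), and 9 of 9 tested members fell (0 up and 9 down adjusted over the list alone), including the receptor genes Il1r1 (-3.39) and Ccr6 (-1.05). The Th1 list was at -0.97 (percentile 0), and 2 of 9 tested members rose, 5 fell and 2 did not pass (2 up and 5 down adjusted over the list alone). Tbx21 (-2.50), Ifng (-2.04) and Il18r1 (-1.59) fell, whereas the chemokine receptor gene Cxcr3 (0.77) rose. Ifng, Ccr9 and Fasl were also among the leading genes of an unnamed Tconv cluster of 313 cells, beside Zbtb16 and Il4. A Cd4 UMI was found in 20.4% of the cells of that cluster, so some can be in the gate. Their part in the gated ratios was not tested.

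The NF-kB and TNF receptor list was at 0.57 (percentile 99.9), and 6 of 11 tested members rose and 5 did not pass (7 up and 0 down adjusted over the list alone), led by Tnfrsf1b (1.90), Icam1 (1.11), Bcl3 (0.95) and Nfkbia (0.90). The T cell receptor signalling list was at -0.16 (percentile 1.98), and 6 of 17 tested members fell and 11 did not pass (0 up and 7 down adjusted over the list alone). The kinase gene Zap70 (-1.07) fell, as did Ptpn22 (-0.97) and Themis (-0.71). This median was higher in Treg (0.18) when cells without a Cd4 UMI were let in. In the receptor response list (median 0.04, and -0.07 with ribosomal protein, mitochondrial and receptor genes left out of the totals), 4 of 10 tested members rose, 1 fell and 5 did not pass (4 up and 1 down adjusted over the list alone). Irf4 (1.36), Cd5 (1.28) and Nr4a1 (1.24) rose, and Myc (-1.60) fell. The dissociation stress list was at -0.51 (percentile 0.25), and 1 of 11 tested members rose, 4 fell and 6 did not pass (1 up and 6 down adjusted over the list alone). Fosb (-0.89), Klf6 (-0.72) and Fos (-0.64) fell, and Junb was lower without passing (-0.61, adjusted p 0.063).

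In the follicular helper list (median 0.40, percentile 95.5), 3 of 7 tested members rose, 2 fell and 2 did not pass (3 up and 2 down adjusted over the list alone). Tox (2.24) and Sh2d1a (0.57) rose, and Tbc1d4 (-1.80) and Tox2 (-1.07) fell. In the Th2 list (median 0.34, percentile 87.7), 1 of 5 tested members rose, 1 fell and 3 did not pass (1 up and 1 down adjusted over the list alone). The IL-33 receptor gene Il1rl1 rose (4.93; 45.7 against 1.5 CPM), while Ccr8 (0.56, adjusted p 0.307), Gata3 (0.12, 0.646) and Ccr4 (0.07, 0.863) did not pass. The inflammatory cytokine list was at -0.22 (percentile 6.97), and 1 of 9 tested members rose, 4 fell and 4 did not pass (1 up and 4 down adjusted over the list alone). Csf1 (1.47) rose, and Il2, Tnfsf8 and Tnfsf11 (-1.30) fell. The homing list was at -0.14 (percentile 7.48), and 2 of 9 tested members rose, 3 fell and 4 did not pass (3 up and 4 down adjusted over the list alone). Ccr2 rose (1.43), and the gut-homing receptor gene Ccr9 (-1.44) and the integrin genes Itgal (-0.78) and Itga4 (-0.73) fell.

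The interferon response list was at 0.14 (percentile 71.5), and 3 of 12 tested members rose, 2 fell and 7 did not pass (3 up and 2 down adjusted over the list alone). Ifi27l2a (1.91) and Zbp1 (0.72) rose, and Slfn1 (-1.72) and Slfn5 (-1.11) fell. In the glycolysis list (median 0.18, percentile 80.3), 4 of 13 tested members rose and 9 did not pass (4 up and 0 down adjusted over the list alone): the glucose transporter gene Slc2a3 (2.05), Tpi1 (1.0), Pkm (0.60) and Gapdh (0.48). In the oxidative phosphorylation list (median -0.05, percentile 12.7), 2 of 14 tested members rose, 2 fell and 10 did not pass (2 up and 2 down adjusted over the list alone). Sdhb (0.46) and Ndufb8 (0.31) rose, and Uqcrq (-0.26) and Cox7c (-0.25) fell. The medians of these 3 lists lay inside their random ranges.

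**Figure D2:**
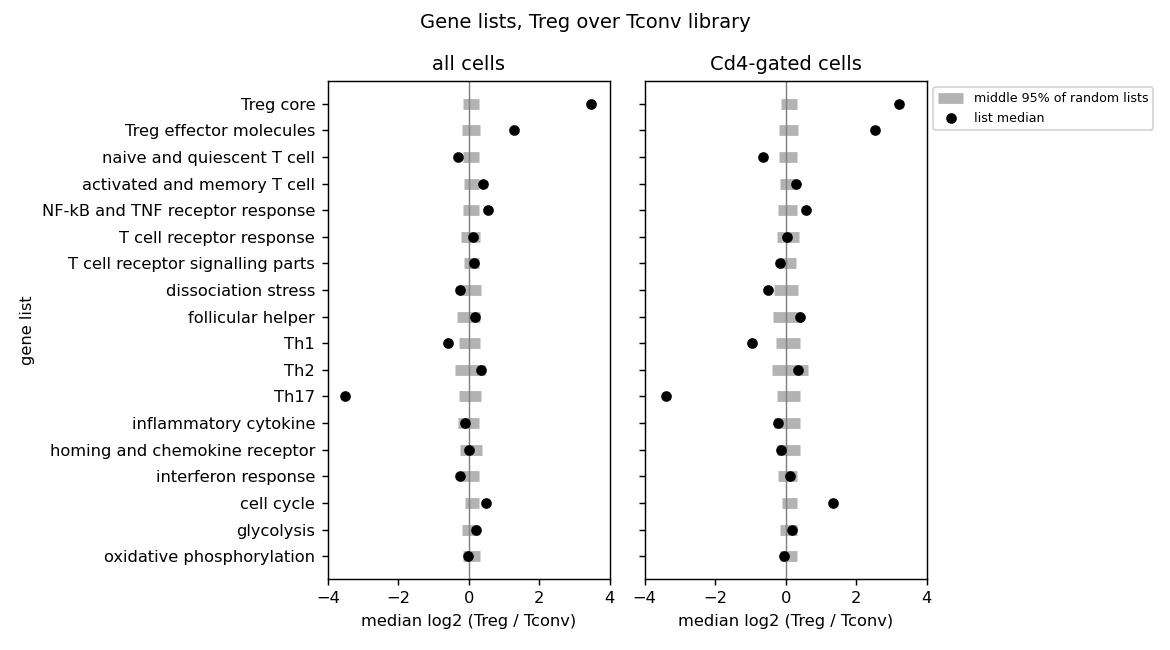
Median log2 ratio of Treg to Tconv for the 18 function lists in all cells and in Cd4-gated cells (points), with the middle 95% of 10000 matched random lists as grey bars. The core Treg list (3.46 and 3.20) and the Th17 list (-3.50 and -3.40) lie farthest from 0.

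Markers of other cell types were measured in the same gated sums. In the B cell list (median 0.69), 4 of 7 tested members rose and 3 did not pass (4 up and 0 down adjusted over the list alone). Cd79b (1.47), H2-Ab1 (0.69), Cd74 (0.60) and H2-Aa (0.55) rose, and Cd79a was not past the test (0.51, 0.202). The median fell below 0 when the gate was changed (-0.33 with any Cd4 level and -0.58 for Treg cells with a Foxp3 UMI against Tconv cells without one). In the CD8 T list (median -2.41), 3 of 8 tested members rose and 5 fell (3 up and 5 down adjusted over the list alone). The cytotoxic genes Gzmk (2.52), Gzma (1.72) and Prf1 (1.60) rose, and the NK receptor genes Klrd1 (-4.63) and Klrk1 (-4.11) fell with Xcl1 (-3.34) and Ctsw (-2.41). In the CD4 T list (median 1.81), 3 of 5 tested members rose, 1 fell and 1 did not pass (3 up and 1 down adjusted over the list alone). Ctla4, Tnfrsf4 (3.41) and Izumo1r (1.81) rose, and Cd40lg fell. The 3 that rose are also in the core Treg list, so this median repeats that list. In the myeloid list (median 0.07, and -0.05 with ribosomal protein, mitochondrial and receptor genes left out of the totals), 1 of 6 tested members rose and 5 did not pass (2 up and 1 down adjusted over the list alone). Ifitm3 was the 1 that rose (0.40). The erythroid list was at -0.57, and 0 of 5 tested members passed (0 adjusted over the list alone); this median was 1.98 without cells with at least 2 B cell or myeloid markers and 0.31 with at least 2 Cd4 UMIs. In the gamma-delta T list, 1 of 1 tested members fell (0 up and 1 down adjusted over the list alone), and in the NK and NKT list, 2 of 3 tested members fell and 1 did not pass (0 up and 2 down adjusted over the list alone). In the plasma cell list, 0 of 2 tested members passed (0 up and 1 down adjusted over the list alone), and in the dendritic cell list, 0 of 2 tested members passed (0 adjusted over the list alone). The platelet list had 0 measured members.

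Across all kept cells, with medians of 2730 UMIs per cell in Treg and 3136 in Tconv, the same classes of genes led. Foxp3 was at 509 CPM in Treg and 2.22 in Tconv (log2 7.84, 7.31 to 8.43; edgeR log2 fold change 7.73 ± 0.239, SE; adjusted p 1.76e-04). It was followed by Penk (6.93), Neb (5.57), Klrg1 (5.15), Rln3 (4.74), Ctla4 (4.44), Tnfrsf9 (4.36), Dusp4 (4.18), Gzmb (3.92) and Tnfrsf4 (3.86), as log2 ratios, all of which rose. Il2ra was 11-fold higher (187 against 17 CPM; 197 ± 7.14 and 19.1 ± 0.602 over hashtag sets). Il22 had the lowest ratio and was 87.3-fold lower (0.819 against 71.5 CPM; adjusted p 0.00132), followed by Il17a (-5.23), Il17f (-4.56), Cxcr6 (-4.41), Tnfsf8 (-3.32), Cd40lg (-3.24), Tmem176a (-3.10), Ehd3 (-3.03), Tcf7 (-2.97) and Tmem176b (-2.88). Cd4 fell slightly (114 against 144 CPM; log2 -0.33; adjusted p 0.0177), and Cd8a (2.58 against 5.16; adjusted p 0.176) and Cd8b1 (26.9 against 23.3; 0.95) did not pass.

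Of 11199 genes, 536 were at least 2-fold higher and 524 at least 2-fold lower in Treg, of which 424 and 338 passed edgeR in the same direction. In edgeR 1449 genes rose and 1269 fell of 11306 tested. The higher genes were 50.6% of the 2-fold genes with library totals, and 41.9% without ribosomal protein, mitochondrial and receptor genes in the totals (476 higher and 661 lower). They were 62% without cells with at least 2 B cell or myeloid markers (589 higher and 361 lower) and 63.1% under the T cell gate (675 and 395). That gate, which also drops T cells with few Cd3 UMIs, was passed by 54.8% of the kept Treg and 62.7% of the kept Tconv cells. The all-cells sums and list medians therefore also hold other cell types. In Tconv, an unnamed cluster of 29 cells led by Ctsg, Mpo and Car1 had a median of 35066 UMIs per cell, against 3136 in the library.

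Among the lists in all cells, the core Treg list (median 3.46) had 16 members up and 1 down of 17 (16 up and 1 down adjusted over the list alone), led after Foxp3 by Gpr83 (5.38), Ikzf4 (4.53) and Ctla4. In the effector list (median 1.28), 9 of 13 tested members rose and 4 did not pass (10 up and 0 down adjusted over the list alone). Areg (3.47) and Tigit (2.76) rose. In the cell cycle list (median 0.48), 14 of 17 tested members rose and 3 did not pass (15 up and 0 down adjusted over the list alone). Mki67 rose, at 332 against 201 CPM (0.72) beside Pclaf (0.87) and Stmn1 (0.85). In the naive list (median -0.32), 4 of 15 tested members rose, 5 fell and 6 did not pass (4 up and 9 down adjusted over the list alone). Nsg2 fell (-4.10), and Igfbp4 was lower without passing (-1.73, adjusted p 0.0519). In the activated list (median 0.40), 10 of 18 tested members rose, 4 fell and 4 did not pass (11 up and 4 down adjusted over the list alone). Icos (1.64) and S100a10 (1.55) rose, and Id2 (-1.93) fell. In the Th17 list (median -3.50), 8 of 9 tested members fell and 1 did not pass (0 up and 9 down adjusted over the list alone). Il23r (-3.50) and Il1r1 (-3.51) fell, and Ccr6 did not pass (-0.59). In the Th1 list (median -0.60), 2 of 11 tested members rose, 5 fell and 4 did not pass (2 up and 6 down adjusted over the list alone). Ifng (-2.25), Tbx21 (-1.87) and Il12rb2 (-1.56) fell.

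In the NF-kB list of all cells (median 0.55), 6 of 11 tested members rose and 5 did not pass (8 up and 0 down adjusted over the list alone), led by Tnfrsf1b (1.59), Icam1 (1.21), Nfkbia (1.04) and Bcl3 (0.96). In the receptor response list (median 0.10), 2 of 12 tested members rose, 1 fell and 9 did not pass (4 up and 2 down adjusted over the list alone). Cd5 (1.59) and Cd6 (1.17) rose, Myc fell (-1.17), and Nr4a1 did not pass (1.15, adjusted p 0.0724). In the receptor signalling list (median 0.15), 3 of 17 tested members rose, 4 fell and 10 did not pass (3 up and 4 down adjusted over the list alone). Cd247 (0.67) rose, and Ptpn22 (-0.76) and Zap70 (-0.61) fell. In the dissociation list (median -0.26), 1 of 12 tested members rose and 11 did not pass (1 up and 0 down adjusted over the list alone). Zfp36 was the 1 that rose (0.56); Fosb (-0.76), Atf3 (-0.65) and Dusp1 (0.48) did not pass. In the follicular helper list (median 0.18), 3 of 9 tested members rose, 1 fell and 5 did not pass (3 up and 1 down adjusted over the list alone), among them Tox (2.29), Slamf6 (0.76) and Sh2d1a (0.68) up and Tbc1d4 (-1.27) down. In the Th2 list (median 0.36), 1 of 5 tested members rose, 1 fell and 3 did not pass (4 up and 1 down adjusted over the list alone). Il1rl1 rose (3.75) and Il4 fell (-3.20), and Ccr8 (0.82) and Ccr4 (0.36) did not pass.

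In the cytokine list of all cells (median -0.10), 3 of 10 tested members rose, 3 fell and 4 did not pass (3 up and 3 down adjusted over the list alone). Csf1 (0.85) rose, and Il2 (-5.54) and Csf2 (-2.96) fell. In the homing list (median 0.00, and -0.09 with ribosomal protein, mitochondrial and receptor genes left out of the totals), 3 of 9 tested members rose, 3 fell and 3 did not pass (3 up and 3 down adjusted over the list alone). Ccr2 (1.36) and Selplg (0.60) rose, and Ccr9 (-1.88) and Itgal (-0.57) fell. In the interferon list (median -0.26), 4 of 14 tested members rose, 2 fell and 8 did not pass (4 up and 2 down adjusted over the list alone). Ifi27l2a (2.06) rose, and Slfn1 (-1.20) and Slfn5 (-0.79) fell; this median was 0.21 under the T cell gate. In the glycolysis list (median 0.19), 3 of 14 tested members rose and 11 did not pass (4 up and 0 down adjusted over the list alone). Slc2a3 (1.44) and Pkm (0.48) rose, and Hk2 (-0.80) and Gapdh (0.30) did not pass. In the oxidative phosphorylation list (median -0.04), 1 of 14 tested members rose and 13 did not pass (1 up and 0 down adjusted over the list alone). Sdhb was the 1 that rose (0.48).

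The hashtag as a block changed some of these calls. With it, edgeR called 1880 higher and 1769 lower genes in all cells and 1421 higher and 1274 lower genes in Cd4-gated cells. Of 14 tested genes of all cells that the naming rule gave and that did not pass, 9 passed with the block: Nr4a1 (adjusted p 7.75e-05), Dusp1 (3.56e-04), Fosb (5.89e-04), Ccr8 (0.00806), Atf3 (0.00954), Igfbp4 (0.0108), Gapdh (0.0165), Cd8a (0.0213) and Ccr4 (0.0375). Ccr6, named outside the rule, passed as well (0.00157). In Cd4-gated cells 2 of 4 such genes passed, Junb (2.86e-11) and Ccr8 (0.0224). Dusp1 was higher in ZAC2 than in ZAC1 in both libraries, at 1126 against 751 CPM in Treg and 804 against 501 CPM in Tconv.

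Other cell types were present in both libraries before gating. In the B cell list of all cells (median -0.38), 2 of 11 tested members fell and 9 did not pass (0 up and 6 down adjusted over the list alone). Ms4a1 (-0.52) and Cd74 (-0.35) fell, while the median was 1.35 once cells with at least 2 B cell or myeloid markers had been left out and 1.40 under the T cell gate. Both filters drop cells by these same genes, so these 2 medians hold only the B cell UMIs that the filters leave. In the gamma-delta T list (median -3.15), 3 of 5 tested members fell and 2 did not pass (0 up and 3 down adjusted over the list alone). Tcrg-C2 (-4.32), Tcrg-C1 (-3.32) and Tcrg-C4 (-3.15) fell, and the delta chain gene Trdc did not pass (-0.11). In the CD8 T list (median -1.0), 2 of 11 tested members rose, 4 fell and 5 did not pass (2 up and 5 down adjusted over the list alone). Gzmk (1.86) rose, and Xcl1 (-3.41) fell. Cd8a (-1.0) and Cd8b1 (0.21) did not pass. Xcl1 and Ctsw were also among the leading genes of an unnamed Tconv cluster of 313 cells, beside Zbtb16, Ifng and Il4. The CD8 T list therefore does not measure the content of CD8 T cells. In the CD4 T list (median 1.36), 3 of 6 tested members rose, 2 fell and 1 did not pass (3 up and 2 down adjusted over the list alone). The 3 that rose, Ctla4, Tnfrsf4 and Izumo1r, are also in the core Treg list, and Cd4 and Cd40lg fell. This median therefore does not measure the content of CD4 T cells. In the erythroid list (median -0.55), 5 of 5 tested members fell (0 up and 5 down adjusted over the list alone), among them Hbb-bt (-0.61); without cells with at least 2 B cell or myeloid markers this median was 0.17. In the myeloid list (median -0.67), 1 of 10 tested members fell and 9 did not pass (0 adjusted over the list alone), and in the NK and NKT list (median -0.84), 0 of 7 tested members passed (0 adjusted over the list alone). In the plasma cell list (median -0.52), 0 of 5 tested members passed (0 adjusted over the list alone), and in the dendritic cell list (median -0.06), 0 of 4 tested members passed (0 adjusted over the list alone). As in the gate, the platelet list had 0 measured members.

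To compare detection per cell at equal depth, cells were thinned to 1500 UMIs, which left 1026 Cd4-gated Treg and 974 Tconv cells (149 and 76 left out; medians before thinning 3713 and 3459 UMIs). A Foxp3 UMI was found in 57.4% of the Treg cells (95% interval 54.3 to 60.5; 57 ± 3.89 over hashtag sets) and in 0.205% of the Tconv cells (0.0249 to 0.740); unthinned, the shares were 74.6% and 0.476%. In B-marker cells, which should lack Foxp3, the share was 2.63% of 228 cells in the Treg library (median 2840 UMIs) and 0 of 287 cells in the Tconv library (median 2847 UMIs), which allows a share of up to 1.05%. The other Treg genes were detected in 41.9% against 5.75% (Ikzf2), 34.8% against 2.67% (Ctla4), 28.6% against 0.513% (Klrg1), 28.4% against 1.54% (Gzmb) and 27.3% against 2.26% (Il2ra). Their shares in the B-marker cells of the Treg library were 1.32%, 1.75%, 0.877%, 0.877% and 0.439%.

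Mki67 was found in 15.5% against 4.83% of the gated cells (3.95% and 3.14% of B-marker cells). Tcf7 was found in 5.07% against 38.3%, Cxcr6 in 1.17% against 27.1%, Il17a in 0.195% against 6.67% and Ifng in 0.877% against 5.65%. In the B-marker cells of the Tconv library these shares were 1.39% for Tcf7, 0.348% for Cxcr6, 0.697% for Il17a and 0 of 287 cells for Ifng, which allows a share of up to 1.05%. In the B-marker cells of the Treg library, Il17a was found in 0 of 228 cells, which allows a share of up to 1.32%, and Cxcr6 in 0.439% (0.0111 to 2.42). The Cd44 shares had overlapping intervals (17.5% and 19.5%). An Il10 UMI was found in 0 of 1026 Treg cells, which allows a share of up to 0.292%, and in 0 of 974 Tconv cells, which allows 0.308%.

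Among all kept cells (3402 Treg and 2736 Tconv cells at 1500 UMIs), Foxp3 was found in 50.7% (49 to 52.4; 52.1 ± 1.41) and 0.292% (0.126 to 0.575), and Cd3e in 77.5% and 70.4%. Cd4 was found in 16.5% and 21.8%, Cd8a in 0.235% and 0.402%, Cd8b1 in 3.62% and 3.25% and Trdc in 0.353% and 0.658%. Cd8a was thus rare in both libraries, although the Tconv sort did not exclude CD8 T cells. Cd8b1 was found more often, and the detection rates of both genes in CD8 T cells were not measured. The B cell gene Cd79a was found in 8.38% and 10.4% and the myeloid gene Lyz2 in 3.06% and 5.52%, against 1.75% and 0.821% and 0.585% and 1.75% within the Cd4 gate. The receptor genes Pdcd1 (2.06% and 1.79%) and Cxcr5 (1.85% and 1.75%) were rarely detected.

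**Figure D3:**
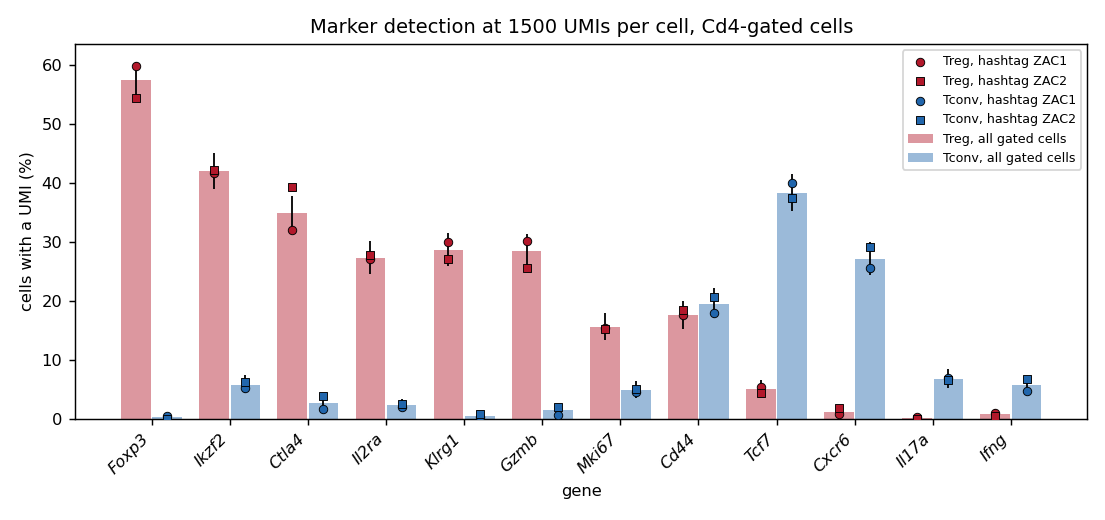
Percent of Cd4-gated cells with a UMI of each of 12 genes after thinning to 1500 UMIs, as bars for all cells of a library with 95% Clopper-Pearson intervals and points for the hashtag sets. Foxp3 reached 57.4% in Treg and 0.205% in Tconv, and Tcf7 5.07% and 38.3%.

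Cytokine transcripts were found in parts of the Cd4-gated Tconv cells. An Il17a, Il17f or Il22 UMI was found in 212 of 1050 Tconv cells (20.2%, 17.8 to 22.7; 21 and 19.1% of the hashtag sets) and in 16 of 1175 Treg cells (1.36%), without thinning. An Ifng UMI was found in 91 Tconv cells (8.67%) and 27 Treg cells (2.30%), and an Il2 UMI in 99 (9.43%) and 2 (0.170%). An Il10 UMI was found in 3 Treg cells (0.255%, 0.0527 to 0.744) and 0 Tconv cells, which allows a share of up to 0.286%. A UMI of Ifng beside 1 of the type 17 cytokines was found in 7 Tconv cells (0.667%) and 0 Treg cells, which allows a share of up to 0.255%.

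The V genes carried by Treg and Tconv cells differed. A single top Trbv gene was assigned to 1013 Treg and 899 Tconv cells of the Cd4 gate. Trbv26 was carried by 115 Treg cells (11.4%, 9.46 to 13.5) and 9 Tconv cells (1.0%, 0.459 to 1.89), with 14.1 and 7.07% and 1.20 and 0.885% in the hashtag sets ZAC1 and ZAC2. Trbv3 was also more frequent in Treg (9.58% against 2.34%). Trbv31 (6.81% against 13.8%), Trbv13-2 (7.70% against 14%) and Trbv29 (3.75% against 8.68%) were more frequent in Tconv. The Trbv29 difference lay mostly in ZAC2 (4.41 and 2.09% of Treg and 5.26 and 12.2% of Tconv cells in ZAC1 and ZAC2). Summed over all Trbv genes, the usage of Treg and Tconv differed by 34.5 percentage points within ZAC1 and 32.2 within ZAC2 (total variation distance), and the hashtag sets of 1 library differed by 21.4 in Treg and 15.9 in Tconv.

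For Trav, assigned in 796 Treg and 659 Tconv cells, the distance between Treg and Tconv (26.2 and 33.8 points) overlapped that between hashtag sets (27.4 in Treg and 36.2 in Tconv). The 5 Trav genes with the largest differences were Trav4-4-dv10 (4.52% against 9.56%), Trav5-1 (4.77% against 1.52%), Trav5-4 (4.27% against 1.82%), Trav13-1 (4.65% against 2.28%) and Trav2 (0.754% against 2.88%). Hashtag sets parted on several of these, with Trav4-4-dv10 at 3.64 and 14.5% in Tconv and Trav5-1 at 7.41 and 0.987% in Treg.

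**Figure D4:**
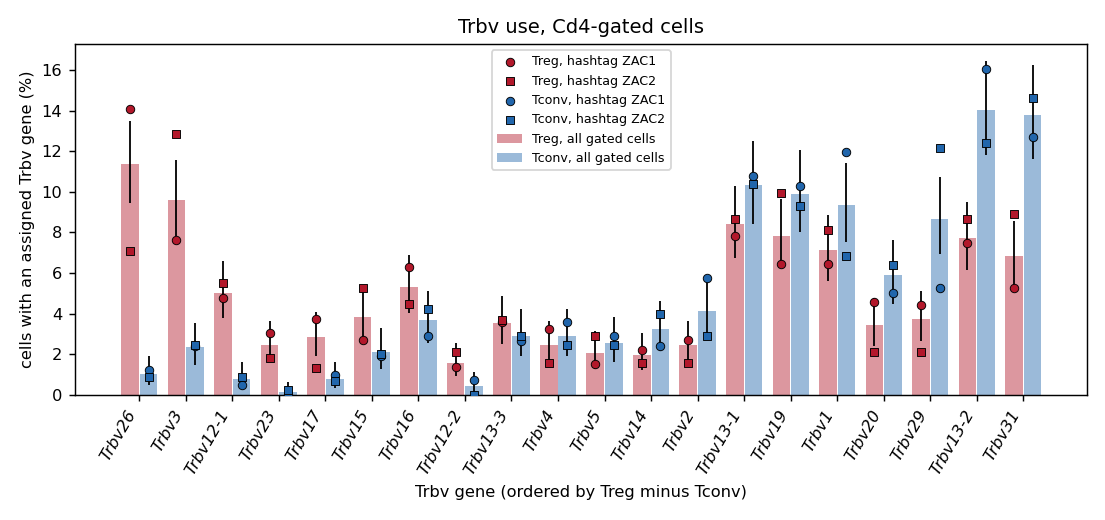
Percent of Cd4-gated cells assigned to each of 20 Trbv genes with at least 10 cells, as bars per library with 95% Clopper-Pearson intervals and points for the hashtag sets. Trbv26 stands at 11.4% in Treg and 1.0% in Tconv, and Trbv31 at 6.81% and 13.8%.

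Each library was also clustered by itself, and cluster sizes were not compared between libraries. In Tconv, a Th17-like cluster led by Acsbg1, Il17re and Lgals3 held 645 cells (21.3%; 22.8 and 21.9% of the hashtag sets), and a naive T-like cluster led by Izumo1r, Cd27 and Ccr7 held 522 cells (17.2%). A cycling cluster held 97 cells (3.20%), and an unnamed cluster of 313 cells was led by Xcl1, Fgl2 and Ccr9 with Ifng, Zbtb16 and Il4 among its leading genes. The largest of the 10 unnamed clusters, of 596 cells, was led by Itgb1 and Cd247. In Treg, an unnamed cluster of 1073 cells was led by Ly6a, Areg and Gzmb, and another of 814 cells by Cyp4f18, Bcl2 and Izumo1r. An activated T-like cluster held 603 cells (14.6%), the cycling clusters 428 (10.4%) and a Treg-like cluster led by Penk, Ccr8 and Tnfrsf9 109 (2.65%). The name Treg-like rests on 2 core Treg genes among its leading genes, Tnfrsf9 and Tnfrsf4. It does not mean that the other clusters are not Treg cells. The Treg-like share differed between the hashtag sets, at 1.37% in ZAC1 and 4.56% in ZAC2. Without thinning, a Foxp3 UMI was found in 97.0% and 91.2% of the cells of the cycling clusters (medians of 7300 and 10458 UMIs). The share was 84.9% in the cluster led by Ly6a (median 2939), 78.0% in the Treg-like cluster (median 2272), 76.6% in the activated T-like cluster (median 3608) and 59.95% in the cluster of 814 cells (median 2018). It was 65.5% in an unnamed cluster of 58 cells led by Aspm, Mki67 and Cenpf (median 2137) and 53.6% in another of 345 cells led by Neb and Macf1 (median 794), so these shares were not taken at equal depth. B cell-like clusters held 275 Treg and 278 Tconv library cells (6.68% and 9.18%), erythroid-like clusters 135 and 134, myeloid-like clusters 60 and 53 and plasma cell-like clusters 16 and 22. Both hashtags were carried by 26.4% of the myeloid-like and 19.4% of the erythroid-like cells of Tconv.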

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

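The alternatives to the edgeR test, the T cell gate and the hashtag and haemoglobin filters were chosen after seeing the data. Of 488 list medians under alternatives 387 stayed within their spread, 92 moved and 9, whose main value lay outside the random range, changed sign; of 60 counts by fold 47, and of 32 counts by test 23, stayed within 1.5 times the reported count. Of 108 marker shares 73 moved, of 30 V gene values 4, and of 4 cluster counts 0. A gene minimum of 10 UMIs gave 925 higher and 1054 lower of 13562 genes in all cells and 1006 and 972 of 11420 in Cd4-gated cells. A minimum of 200 gave 329 and 255 of 8808 genes in all cells and 282 and 146 of 5398 in Cd4-gated cells. A larger part of the tested genes was thus called at the lower minimum, so the number tested does not account for these counts by itself. Thinning to 1500 UMIs left 323 lower genes in all cells, and 374 higher and 187 lower in Cd4-gated cells; a gate of at least 2 Cd4 UMIs left 366 and 251. Both leave fewer UMIs by construction. DESeq2 called 772 lower genes in all cells and 514 higher and 409 lower in Cd4-gated cells, and the cause was not tested. Without 1 hashtag set, where the lone set of a library is assumed to vary like the others, edgeR called 664 to 970 higher and 556 to 870 lower genes in all cells, and 1001 to 1255 and 818 to 1081 in Cd4-gated cells. The all-cells counts moved by over 1.5 times without Treg ZAC1 (664 and 556), Tconv ZAC1 (752 and 631) and Tconv ZAC2 (768 and 687). Such medians in all cells were those of the interferon list under the T cell gate (0.21), the B cell list under that gate (1.40) and without cells with at least 2 B cell or myeloid markers (1.35), and the erythroid list without those cells (0.17). In Cd4-gated cells they were the receptor signalling list (0.18) and the B cell list (-0.33) with any Cd4 level, the B cell list between Treg cells with and Tconv cells without a Foxp3 UMI (-0.58), and the erythroid list without B cell or myeloid marker cells (1.98) and with at least 2 Cd4 UMIs (0.31). For these sign changes the cause was not tested, but the T cell gate and the marker filter drop cells by the B cell list's own genes. The Foxp3 share of kept cells moved with depth, to 40.1% in Treg and 0.104% in Tconv at 1000 UMIs, 61.6% in Treg at 2500 UMIs, and 64.4% and 0.594% without thinning. Rare cytokines such as Il10 could not be compared at this depth.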

Other observations

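The gene groups and the comparison of hashtag sets in this part, and the tests on gamma-delta T cells and a single mouse, were chosen after the results had been seen. In Cd4-gated cells, the medians of the ligand and receptor genes of the TNF family went in opposite directions. These groups repeat earlier results in part. Tnfsf8 and Cd40lg were among the 12 lowest genes, and Tnfrsf9, Tnfrsf4 and Tnfrsf18 are in the core Treg list. Fasl was also a leading gene of the unnamed Tconv cluster with Zbtb16 and Il4. Of 10 tested ligand genes 6 fell in Treg and 0 rose (median log2 ratio -0.99): Fasl (-3.93), Tnfsf8 (-3.75), Tnfsf14 (-3.73), Cd40lg (-3.45), Tnfsf11 (-1.30) and Tnf (-0.67), while Ltb did not pass (0.13). Of 15 tested receptor genes 8 rose and 2 fell (median 1.49), led by Tnfrsf9 (4.45), Tnfrsf4 (3.41), Cd27 (2.14) and Tnfrsf18 (2.01), with Tnfrsf25 (-1.35) and Tnfrsf26 (-1.61) down. Genes of ribosome biogenesis were lower in Treg although its cell cycle genes were higher: 22 of 29 fell and 0 rose (median -0.78), among them Rrp15 (-1.72), Rrp9 (-1.35), Fbl (-1.04), Nop10 (-0.94) and Npm1 (-0.41), while Ncl did not pass (-0.06).

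The hashtag sets differed within each library, taken as 1 mouse each and so with no test. In Cd4-gated Treg cells the interferon list was higher in ZAC2 than in ZAC1 (median log2 0.79) and the cell cycle list lower (-0.57). Isg15 was at 33.6 and 97 CPM (log2 1.53, 1.17 to 1.90) in ZAC1 and ZAC2, Ly6a at 269 and 670.1 CPM (log2 1.32, 1.19 to 1.45) and Ube2c at 520.1 and 249 CPM (log2 -1.06, -1.22 to -0.91). In Tconv the cell cycle list went the other way (0.21). The median of the interferon list was smaller (0.16), but 5 of its 11 members were at least 1.5-fold higher in ZAC2, against 6 of 11 in Treg. Isg15 was alike in Tconv, at 44.8 and 44.6 CPM (log2 -0.01, -0.46 to 0.45), but Ifi27l2a was at 234 and 644 CPM (log2 1.46, 1.30 to 1.62). Other lists were higher in ZAC2 in both Treg and Tconv: dissociation stress (0.36 and 0.51), T cell receptor response (0.63 and 0.38) and NF-kB (0.34 and 0.23). Handling was therefore not separated from the mice. Of 7382 genes in Treg 50 were at least 2-fold higher and 44 lower in ZAC2, and of 6784 in Tconv 54 and 18.

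An Il17a, Il17f or Il22 UMI was found in 212 Cd4-gated Tconv cells. Gamma-delta T cells could bring such UMIs. At 1500 UMIs per cell 32.7% of the cells with such a UMI had a UMI of the alpha chain gene Trac (66 of 202, 26.3 to 39.6). The share was 32.3% of the other gated cells (249 of 772, 29.0 to 35.7). This argues against gamma-delta T cells as most of these cells only if gamma-delta T cells seldom carry a Trac UMI. Neither that rate nor free Trac RNA was measured. A UMI of Tcrg-C1, Tcrg-C2 or Tcrg-C4 was found in 6.13% of the 212 cells (13 cells) and in 5.73% of the other gated cells without thinning. Tcrg-C1 fell in Treg within the gate (-2.81), so gamma-delta T cells among the 212 cells stay open. An earlier test on Trdc, which was found in 2 of the 212 cells, was dropped because its detection rate in gamma-delta T cells was not known. A single mouse is argued against only if the hashtags are the 2 mice, which the labels do not state. In that case the lower of both hashtag sets still had 19.1% of such cells. A response to the arthritis stays an untested explanation, as no spleen without arthritis was compared here.

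Trbv26 was more frequent in Treg. A few expanded clones are unlikely, since the most frequent Trav gene, with duplicated copies merged, was Trav3-3 and was carried by 9.09% of the Trbv26 cells with a Trav gene (6 of 66, 3.41 to 18.7; 35 merged Trav genes). A Trbv26 UMI was found in 0 of 228 B-marker cells of the Treg library, which allows a share of up to 1.32%. In gated cells the share was 9.26%. The B-marker cells were chosen without a Cd3 UMI, so cells with free T cell RNA may be missing among them. In the B cell-like Treg cluster, which had no such filter, 20.7% of cells had a Cd3 UMI and 9.09% a Foxp3 UMI, without thinning. The test therefore cannot exclude free receptor RNA. Selection by endogenous superantigens, which remove Tconv cells with certain V genes, stays open and was not tested, since the V genes tied to it were picked after their shares had been seen.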
